A study of Homo sapiens with 16 samples.

How the data were processed

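RNA was extracted with a column kit from 16 samples, 4 for each combination of cell line (MDA-MB-231 or SUM159PT) and guide (sgNTS or sgYES1), collected 48 h after transfection. Poly-A RNA was purified with oligo-dT beads and copied into cDNA with random hexamers, per the labels' protocols. The protocol covers both directional and non-directional libraries, so it is not settled whether the counting used strand, and overlapping and antisense genes are treated as uncertain. The protein that acts with the guides is not given in the sources used here.

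The authors deposited 1 table of raw counts per gene for each cell line, and these values are whole-number counts with no normalization. Per the submitters' processing notes, reads were aligned to hg38 with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3. The setting of featureCounts for reads that match several places is not given in the sources used here, so genes with near-identical paralogs are uncertain. Each table held 58735 genes, every one of them with the ID, start and end of GENCODE 29, and no entry lacked a gene. Columns were matched to samples by the guide and replicate number in their names and by the cell line of their table.

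Depth (in units of 1e6 counts) ranged from 17.2 to 25.1 in MDA-MB-231 and from 14.4 to 20.9 in SUM159PT. Pairs of libraries within a group differed by more than counting noise (lowest chi-square per degree of freedom 2.33), so none were copies, but this does not show separate cultures. The highest values were those of MDA-MB-231 sgNTS replicate 4 against replicates 1, 2 and 3 (29.1, 19.6 and 9.38), so this library stood apart from its group. Each library was counted as 1 replicate.

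Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after TMM scaling, on genes kept by filterByExpr (smallest count 10, smallest total 15). Each line was fitted on its own 8 libraries with guide as the only term, and the difference between lines was the interaction of line and guide over all 16 libraries. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05, two-sided. CPM values are TMM-scaled and log2 CPM used a prior count of 2. Exceptions are the CPM of leukocyte and endothelial markers, the CPM gained by the inflammatory list and the CPM of olfactory receptor genes, which use library totals alone. Errors are SD of 4 libraries or the SE of the fitted log2 fold change. YES1 was also tested by a two-sided exact permutation of log2 CPM. Genes called in both lines were set beside the overlap of independent lists; the lines share no libraries.

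Fixed gene lists, 32 in number, were written before the data were examined, and 1107 of their 1109 symbols matched the tables. They covered mitosis, FOXM1 targets, S phase and replication, homologous recombination, tubulins and taxane transport, Src-family kinases, Src substrates and adhesion signaling, ERK targets, YAP and TAZ targets, serum response and actin, NF-kB and inflammation, interferon-stimulated genes, NRF2 targets, p53 targets, the BCL2 family, the integrated stress response, endoplasmic reticulum chaperones, heat shock, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, lysosome and autophagy, non-polyadenylated histones, epithelial genes, mesenchymal and matrix genes, and markers of luminal breast, endothelial cells and leukocytes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM at a preset inter-gene correlation of 0.01, and the adjusted p with a correlation estimated from the residuals is given beside each call. Lists overlap, as those of mitosis and FOXM1 targets do.

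The genes named were fixed by rule before the data were examined. They are YES1 and the Src-family kinases, 11 mitotic genes, up to 4 members of a described list with the smallest p, and, for each line, the 8 highest and 8 lowest log2 fold changes among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups. For both lines together they are the 8 genes with the largest shared rise and the 8 with the largest shared fall, ranked by the smaller of both changes under the same filters in each line, and the 8 protein-coding genes with the smallest p of the difference and a mean of at least 5 CPM in each line. Genes outside the rule are said to be so where they appear.

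The code was tested on simulated data made from the means and library sizes of these samples. At each size 100 genes were changed, and shares recovered are of those that passed the filter. In the MDA-MB-231 comparison edgeR recovered 77.0% of 100 changes of 1.5-fold and 94.8% of 97 of 2-fold, with 5 false calls among 15259 genes. In the SUM159PT comparison it recovered 82.8% and 92.9%, each of 99, with 19 false calls among 14309 genes. For the difference between lines it recovered 67.0% and 87.0%, each of 100, with 11 false calls among 13390 genes. A shift of -0.2 in the mitosis list was called in both lines, and 1 other list was called with it, the FOXM1 targets, which share its genes. Simulated genes were drawn independently of one another, so this does not show how the list test behaves where genes vary together. The simulation also changed far fewer genes than were called in the real libraries.

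The alternatives tried were the size factors of DESeq2 1.42.0 and library totals in place of TMM, other filters on low counts, protein-coding genes only, the Wald test of DESeq2, limma-voom, all 16 libraries in 1 fit, stricter thresholds, the replicate number as a block, and leaving out each library in turn. Lists were also tested with an estimated correlation, with fry, which asks whether a list moves one way, and with ranks in cameraPR. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.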

Results

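Poly-A RNA was sequenced from MDA-MB-231 and SUM159PT, established human triple-negative breast cancer lines, which lack the estrogen and progesterone receptors and HER2 amplification. Cells had been transfected by lipofection with a non-targeting guide RNA (sgNTS) or with a guide RNA directed at YES1 (sgYES1), which encodes a tyrosine kinase of the Src family, and were collected 48 h after transfection. Each line and guide was represented by 4 replicates, which made 16 libraries in 4 groups. The title of the series places the experiment in a study of YES1, the fidelity of mitosis and the response to taxanes. No taxane was named for these samples.

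In MDA-MB-231, gene counts summed (in units of 1e6) to 24.6, 19.2, 17.7 and 23.6 in sgNTS replicates 1 to 4 and to 17.3, 17.2, 20.3 and 25.1 in sgYES1 replicates 1 to 4. In SUM159PT, the totals were 15.5, 16.8, 14.4 and 20.9 for sgNTS and 20.5, 15.2, 16.7 and 20.4 for sgYES1. Transcripts of the mitochondrial genome took 4.03% ± 1.26 (SD, n = 4) of the counts in MDA-MB-231 sgNTS, with a lowest value of 2.34% in replicate 4, and 3.78% to 5.08% in sgYES1. The corresponding shares in SUM159PT were 3.49% ± 0.0786 and 3.62% ± 0.114. The biological coefficient of variation between libraries of a group was 5.85% in MDA-MB-231 and 5.66% in SUM159PT. The submitters describe the replicates as technical and nothing in the labels assigns them to separate cultures, so the p-values measure the spread between these samples only.

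YES1 mRNA was lower in every sgYES1 library than in every sgNTS library of the same line. In MDA-MB-231 it fell from 109 ± 3.12 to 43.1 ± 1.14 counts per 1e6 counts (CPM; mean ± SD, n = 4), a log2 fold change of -1.34 (SE 0.04) or a 2.53-fold lower level. In SUM159PT it fell from 92.9 ± 3.78 to 39.4 ± 0.870 CPM, a log2 fold change of -1.24 (SE 0.05) or a 2.36-fold lower level. Transcripts at 39.6% and 42.4% of the sgNTS level were therefore still present in MDA-MB-231 and SUM159PT. The gene (ENSG00000176105) lies on the minus strand of chromosome 18, from 721588 to 812546 in hg38. The edgeR adjusted p was 2.76e-11 in MDA-MB-231 and 1.65e-13 in SUM159PT, and the two-sided exact permutation p was 0.0286 in each line, the smallest that 4 against 4 libraries can give. The log2 effect in SUM159PT minus that in MDA-MB-231 was 0.09 (95% interval -0.04 to 0.21, adjusted p = 0.308), so the lines were not shown to differ in the loss of YES1 mRNA.

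**Figure D1:**
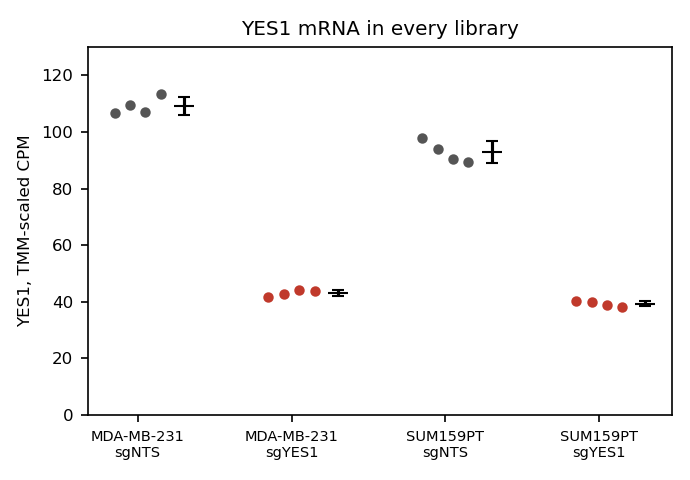
YES1 mRNA in each of the 16 libraries, as CPM after TMM scaling on the y axis. Points are libraries and the bars beside them give the mean and SD of the 4 libraries of a group. The sgNTS libraries lie between 89.4 and 113 CPM and the sgYES1 libraries between 38.3 and 44.3 CPM.

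Other Src-family kinases and their regulator moved little. SRC, the founding member of the family, had log2 fold changes of 0.03 (SE 0.04) in MDA-MB-231 and -0.02 (SE 0.05) in SUM159PT, and FYN had 0.02 (SE 0.05) and 0.18 (SE 0.08), with no value past the threshold. LYN was called lower in MDA-MB-231 (-0.14, adjusted p = 0.0395) and was not called in SUM159PT (0.14, adjusted p = 0.149). CSK, the kinase that phosphorylates the inhibitory tail of Src-family members, was called lower in MDA-MB-231 (-0.13, adjusted p = 0.0405) and higher in SUM159PT (0.10, adjusted p = 0.046). PTK6 and FRK, related kinases, were tested in MDA-MB-231 only and had log2 fold changes of 0.11 and 0.23, neither called. These small calls were fragile. That of LYN ended without MDA-MB-231 sgNTS replicate 2, 3 or 4 or sgYES1 replicate 1, 3 or 4 (adjusted p 0.0598 to 0.12), that of CSK in MDA-MB-231 ended without sgNTS replicate 1 or 4 or sgYES1 replicate 1, 2 or 3 (0.0684 to 0.12), and that of CSK in SUM159PT ended without sgNTS replicate 1, 2 or 4 or sgYES1 replicate 2, 3 or 4 (0.0524 to 0.137). With library totals as the only scaling, neither call in MDA-MB-231 held (adjusted p = 0.168 for each).

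In MDA-MB-231, among protein-coding genes with a mean of at least 5 CPM and no overlap between groups, 5 of the 8 with the highest fold changes encode cytokines or chemokines. CSF3, the growth factor of neutrophils, rose from 2.62 ± 0.526 to 28.7 ± 1.48 CPM (log2 fold change 3.47, SE 0.10), and the cytokine gene IL6 rose from 13.1 ± 0.216 to 74.3 ± 6.65 CPM, 5.69-fold. The interleukin-1 genes IL1A and IL1B rose 8.43-fold and 6.55-fold, and CXCL1, which encodes a neutrophil chemokine and has near-identical paralogs, rose 4.69-fold. ARC, an immediate-early gene best known from neurons, rose 9.18-fold, FOSB, which encodes a subunit of the AP-1 transcription factor, 5.21-fold, and SCG5, which encodes a chaperone of prohormone processing, 4.52-fold. Within the same limits, the lowest fold changes were those of CORO2B, a coronin that binds actin (20.9 ± 1.10 to 7.88 ± 0.843 CPM, log2 fold change -1.41, SE 0.08), and of YES1, followed by KISS1, which encodes kisspeptin (-1.17), LYPD6 (-1.09), MALL (-1.06), TMEM238 (-1.05), FHL1, a LIM-domain protein gene (-1.02), and the cytokine gene IL11 (-0.97).

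Of 15427 genes tested in MDA-MB-231, 6607 changed, 3205 upward and 3402 downward (edgeR quasi-likelihood test, adjusted p under 0.05). With library totals as the only scaling, 3956 rose and 2661 fell, so the share of upward calls moved from 48.5% to 59.8%. At a fold of at least 1.5, 1110 genes rose and 279 fell, and at a fold of at least 2, 500 rose and 36 fell. Most of the 2-fold rises were at a low level. Under 1 CPM 219 rose and 17 fell by 2-fold, at 1 to 10 CPM 233 rose and 14 fell, and over 10 CPM 48 rose and 5 fell. The 4 sgYES1 libraries did not overlap the 4 sgNTS libraries for 39.2% of the genes, where chance gives 2.86%.

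Genes of NF-kB and inflammation rose as a group in MDA-MB-231. Of 31 tested members, 29 rose and 0 fell, both over all genes and adjusted over the list alone, and the median log2 fold change was 0.87. Besides IL6 and CSF3, the members with the smallest p were SOD2, the mitochondrial superoxide dismutase (106 ± 2.10 to 255 ± 6.15 CPM, 2.39-fold), and CXCL8, a neutrophil chemokine (91.8 ± 3.13 to 291 ± 23.6 CPM, 3.17-fold). The set test camera gave adjusted p = 2.77e-18, and adjusted p = 0.0364 with an estimated correlation. Markers of leukocytes were at a low level beside this rise. With CPM of these markers taken over library totals, the 13 markers of that list under 5 CPM in sgNTS summed to 1.92 CPM in sgNTS and 4.04 CPM in sgYES1. CD14 went from 0.839 to 1.99 CPM and ITGAM from 0.290 to 1.16 CPM, 2 markers chosen after their values were seen, while 2 other markers of the list were higher in both groups, CD74 at 340 and 366 CPM and CSF1R at 7.60 and 9.32 CPM.

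Targets of NRF2, the regulator of antioxidant genes, and genes of the integrated stress response were also higher. Of 28 NRF2 targets, 18 rose and 1 fell (22 and 1 adjusted over the list alone; median 0.25). HMOX1, heme oxygenase, rose 2.90-fold and FTL, the light chain of ferritin, rose from 2110 ± 77.8 to 4168 ± 129 CPM, 1.98-fold, although FTL has pseudogenes that can share its reads. Of 39 stress-response genes, 20 rose and 7 fell (20 and 8 adjusted over the list alone; median 0.18). SESN2, a stress-induced inhibitor of mTORC1 signaling, rose 3.22-fold, the transcription factor gene ATF3 2.91-fold, the stress cytokine gene GDF15 2.34-fold, and PPP1R15A, which directs dephosphorylation of eIF2-alpha, 2.09-fold. The camera adjusted p was 1.53e-06 for the NRF2 targets (adjusted p = 0.186 with an estimated correlation) and 0.00153 for the stress-response genes (adjusted p = 0.294 with an estimated correlation).

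Genes of mitosis were lower in MDA-MB-231. Of 90 tested members, 86 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.46. All 11 mitotic genes chosen before the data were examined fell. PLK1, the kinase of mitotic entry and spindle assembly, fell from 182 ± 5.59 to 111 ± 7.78 CPM (log2 fold change -0.71, SE 0.05), and CENPE, the kinetochore motor, from 105 ± 6.72 to 70.1 ± 3.70 CPM (-0.59, SE 0.05). FOXM1, the transcription factor of the G2/M program, had -0.53, the spindle checkpoint genes MAD2L1, BUB1 and TTK had -0.50, -0.48 and -0.47, and CDC20, the activator of the anaphase-promoting complex, had -0.42. The kinesin gene KIF18A had -0.39, the cyclin gene CCNB1 -0.37 and the Aurora kinase genes AURKA and AURKB -0.35 and -0.23. Of 33 FOXM1 targets, a list that shares many genes with that of mitosis, 31 fell and 0 rose, with the same counts adjusted over the list alone (median -0.46), among them KIF20A, a kinesin of cytokinesis (-0.58). Camera gave adjusted p of 3.05e-29 for mitosis (adjusted p = 0.0833 with an estimated correlation) and 1.43e-15 for FOXM1 targets (adjusted p = 0.14 with an estimated correlation).

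S-phase and repair genes fell beside them. Of 57 genes of S phase and replication, 52 fell and 1 rose (54 and 1 adjusted over the list alone; median -0.30). RRM2, a subunit of ribonucleotide reductase, fell from 166 ± 3.66 to 103 ± 3.58 CPM (-0.70, SE 0.04), MCM6, a subunit of the replicative helicase, had -0.61, and the transcription factor gene E2F8 had -0.87. TYMS, thymidylate synthase, had -0.92, a value that is uncertain because TYMS overlaps an antisense gene and lies near YES1. Of 33 genes of homologous recombination, 20 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.24), including BARD1, the partner of BRCA1 (-0.65), and RBBP8, which encodes the end-resection factor CtIP (-0.53). Both lists kept their camera calls under either correlation, with adjusted p of 7.36e-18 and 1.11e-05 at the preset correlation and adjusted p = 0.0364 for each with an estimated correlation.

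Genes of adhesion, the cytoskeleton and lipid synthesis were lower by smaller amounts in MDA-MB-231. Of 37 Src substrates and adhesion genes, 18 fell and 4 rose (20 and 4 adjusted over the list alone; median -0.14), and CAV1, the caveolin of membrane pits, fell from 746 ± 24.3 to 393 ± 17.3 CPM (-0.92, SE 0.04). Of 29 serum-response and actin genes, 18 fell and 2 rose, the same over the list alone (median -0.19), with CNN3, an actin-binding calponin, at -0.50. Of 33 YAP and TAZ targets, 16 fell and 4 rose (17 and 4 adjusted over the list alone; median -0.12), with the receptor kinase gene AXL at -0.40. Of 26 genes of tubulins and taxane transport, 13 fell and 4 rose (15 and 4 adjusted over the list alone; median -0.20), with TUBA1B at -0.53 and TUBB at -0.37, although tubulin genes share reads with close paralogs. Of 18 genes of fatty acid synthesis, 10 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.12), and of 25 of cholesterol synthesis, 11 fell and 2 rose, the same over the list alone (median -0.10).

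The camera adjusted p was 6.81e-05 for serum response and actin, 0.00115 for Src substrates, 0.00256 for fatty acid synthesis, 0.00436 for YAP and TAZ targets and for cholesterol synthesis, and 0.0066 for tubulins. In the same order, with an estimated correlation, the adjusted p was 0.14, 0.407, 0.279, 0.34, 0.294 and 0.294, so none of these 6 calls held. In all, 13 of 31 tested lists passed in MDA-MB-231, 3 upward and 10 downward, and 3 passed with an estimated correlation. Other groupings of the same 8 libraries gave up to 14 lists, so the number of lists is not by itself beyond chance.

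In SUM159PT, within the same limits on class, level and overlap, the 8 genes with the highest fold changes began with ARC, which rose 6.52-fold. HSPA1B and HSPA1A, near-identical genes for the inducible HSP70 chaperone that can exchange reads, rose from 26.2 to 143 ± 11.3 CPM, 5.44-fold (log2 SE 0.16), and from 12.3 ± 6.33 to 62.4 ± 5.18 CPM, 5.01-fold. RRAD, a Ras-related GTPase gene, rose 4.98-fold, PTGES, prostaglandin E synthase, 4.28-fold, and C1S, a protease of the complement system, 4.05-fold. The serum amyloid genes SAA1 and SAA2, again near-identical, rose 3.84-fold and 4.53-fold. Within these limits, the lowest fold changes were those of CHAC1, an enzyme that degrades glutathione (53.9 ± 15.8 to 11.2 ± 1.73 CPM, log2 fold change -2.27, SE 0.16), EGR1, an immediate-early transcription factor (103 ± 47.4 to 25.7 ± 2.94 CPM), ASNS, asparagine synthetase (-1.99), DDIT4, an inhibitor of mTORC1 (716 ± 111 to 180 ± 21.7 CPM, -1.99, SE 0.09), and DMBT1, a secreted scavenger receptor (-1.58). PCK2, a mitochondrial enzyme of phosphoenolpyruvate synthesis, and TSC22D3, a glucocorticoid-induced gene, both had -1.38, and CTH, an enzyme of cysteine synthesis, had -1.31.

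Of 14479 genes tested in SUM159PT, 5701 changed, 2842 upward and 2859 downward. With library totals as the only scaling, 3211 rose and 2454 fell, or 56.7% upward. At a fold of at least 1.5, 683 rose and 371 fell, and at a fold of at least 2, 296 rose and 86 fell. Under 1 CPM 108 rose and 17 fell by 2-fold, at 1 to 10 CPM 160 rose and 47 fell, and over 10 CPM 28 rose and 22 fell. The groups did not overlap for 35.3% of the genes, where chance gives 2.86%. One control library stood apart in several groups of genes. Mean list scores of SUM159PT sgNTS replicate 2, relative to the sgNTS mean, were -0.31 for the integrated stress response, -0.47 for NF-kB and inflammation and 0.20 for heat shock, against 0.02 to 0.16, 0.01 to 0.38 and -0.10 to -0.02 in the other 3 sgNTS libraries.

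Integrated stress response genes fell as a list in SUM159PT. Of 38 tested members, 31 fell and 0 rose (32 and 0 adjusted over the list alone), and the median log2 fold change was -0.57. Besides DDIT4 and PCK2, the members with the smallest p were the genes of serine synthesis PHGDH (122 ± 13.7 to 55.8 ± 5.17 CPM, -1.13, SE 0.07) and PSAT1 (277 ± 38.7 to 134 ± 5.90 CPM, -1.04, SE 0.07). In MDA-MB-231, where the list as a whole was called upward (adjusted p = 0.294 with an estimated correlation), PSAT1 fell (-0.36, SE 0.04), and PHGDH (-0.13) and PCK2 (-0.10) were not called. Of 78 ribosomal protein genes, 55 fell and 1 rose (56 and 1 adjusted over the list alone; median -0.13), with RPL3 at -0.32 and RPLP0 at -0.28, while of 35 genes of ribosome biogenesis 19 rose and 4 fell (20 and 5 adjusted over the list alone; median 0.11). In camera the adjusted p was 3.65e-12, 3.52e-09 and 0.00569 for these 3 lists, and adjusted p = 0.662 for each with an estimated correlation.

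Heat shock, interferon-stimulated and inflammatory genes were higher in SUM159PT. Of 20 heat shock genes, 17 rose and 0 fell, the same over the list alone (median 0.27). HSPA8, the constitutive HSP70, rose from 744 ± 237 to 1857 ± 59.5 CPM, 2.49-fold, and the co-chaperone genes DNAJA1 and DNAJB1 rose 1.84-fold and 1.69-fold. Of 42 interferon-stimulated genes, 18 rose and 2 fell (19 and 2 adjusted over the list alone; median 0.29), among them the antiviral genes OASL (1.08 ± 0.362 to 6.11 ± 1.10 CPM, 5.42-fold) and IFIT3 (1.78 ± 0.227 to 5.22 ± 0.658 CPM, 2.94-fold), the transcription factor gene IRF1 (1.64-fold) and HELZ2, a nuclear coactivator (1.33-fold). Of 24 NF-kB and inflammatory genes, 15 rose and 0 fell, the same over the list alone (median 0.43), with ICAM1, an adhesion receptor for leukocytes, at 2.18-fold and SOD2 at 1.76-fold. IL6 was called at a log2 fold change of 0.51 (adjusted p = 0.036), a call that ended under DESeq2 (adjusted p = 0.269) and without sgNTS replicate 1 or 2 or sgYES1 replicate 1, 2 or 3 (adjusted p 0.0613 to 0.16). Without sgNTS replicate 2 its log2 fold change was 0.29. Camera gave adjusted p of 2.83e-07 for heat shock, 6.15e-05 for interferon-stimulated genes and 0.000611 for NF-kB. With an estimated correlation, the adjusted p was 0.662, 0.0868 and 0.687.

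Mitotic genes were lower in SUM159PT by a small amount. Of 90 tested members, 35 fell and 5 rose, the same over the list alone, with a median log2 fold change of -0.08, and of 33 FOXM1 targets 12 fell and 1 rose, the same over the list alone (median -0.08). Among the 11 mitotic genes chosen beforehand, CENPE (-0.24, adjusted p = 0.0177) and KIF18A (-0.27, adjusted p = 0.0165) passed the threshold. The other 9 had log2 fold changes of -0.11 for BUB1, -0.10 for FOXM1 and for MAD2L1, -0.07 for AURKB, -0.02 for PLK1 and for CCNB1, -0.01 for CDC20, 0.05 for AURKA and 0.06 for TTK, none of which passed. The call of CENPE ended without sgNTS replicate 2 or sgYES1 replicate 2, 3 or 4 (adjusted p 0.0501 to 0.0857, log2 fold change -0.16 without sgNTS replicate 2) and that of KIF18A without sgNTS replicate 2 or sgYES1 replicate 4 (0.0509 and 0.0617). The camera adjusted p was 0.00246 for mitosis and 0.0171 for FOXM1 targets, and adjusted p = 0.687 for each with an estimated correlation. Without sgNTS replicate 2 neither list passed (adjusted p of 0.0563 and 0.108), and the test fry gave adjusted p = 0.0521 for the FOXM1 targets.

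Of 33 genes of homologous recombination in SUM159PT, 9 fell and 1 rose, the same over the list alone (median -0.13), with BARD1 at -0.36 and RBBP8 at -0.32. Of 32 YAP and TAZ targets, 18 fell and 2 rose, the same over the list alone (median -0.21), including AXL (436 ± 10.2 to 281 ± 13.1 CPM, -0.63, SE 0.04) and CYR61, a matricellular protein gene (-0.61, SE 0.05). Of 46 nuclear genes of oxidative phosphorylation, 14 fell and 0 rose, the same over the list alone (median -0.09). Of 18 genes of fatty acid synthesis, 9 fell and 1 rose, the same over the list alone (median -0.15). The camera adjusted p was 9.79e-05 for YAP and TAZ targets, 0.0079 for oxidative phosphorylation, 0.0107 for homologous recombination and 0.0429 for fatty acid synthesis, and in that order the adjusted p was 0.461, 0.687, 0.685 and 0.685 with an estimated correlation. The fatty acid call also ended with library totals (adjusted p = 0.0505) and without sgNTS replicate 1 or 2 or sgYES1 replicate 2 or 3 (0.0563 to 0.0616), and fry gave 0.0521 for oxidative phosphorylation. In all, 12 of 30 lists passed in SUM159PT, 4 upward and 8 downward. With an estimated correlation camera called 0 lists, 2 had an unadjusted p under 0.05, and fry called 18. Another grouping of the same 8 libraries also gave 12 lists.

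**Figure D2:**
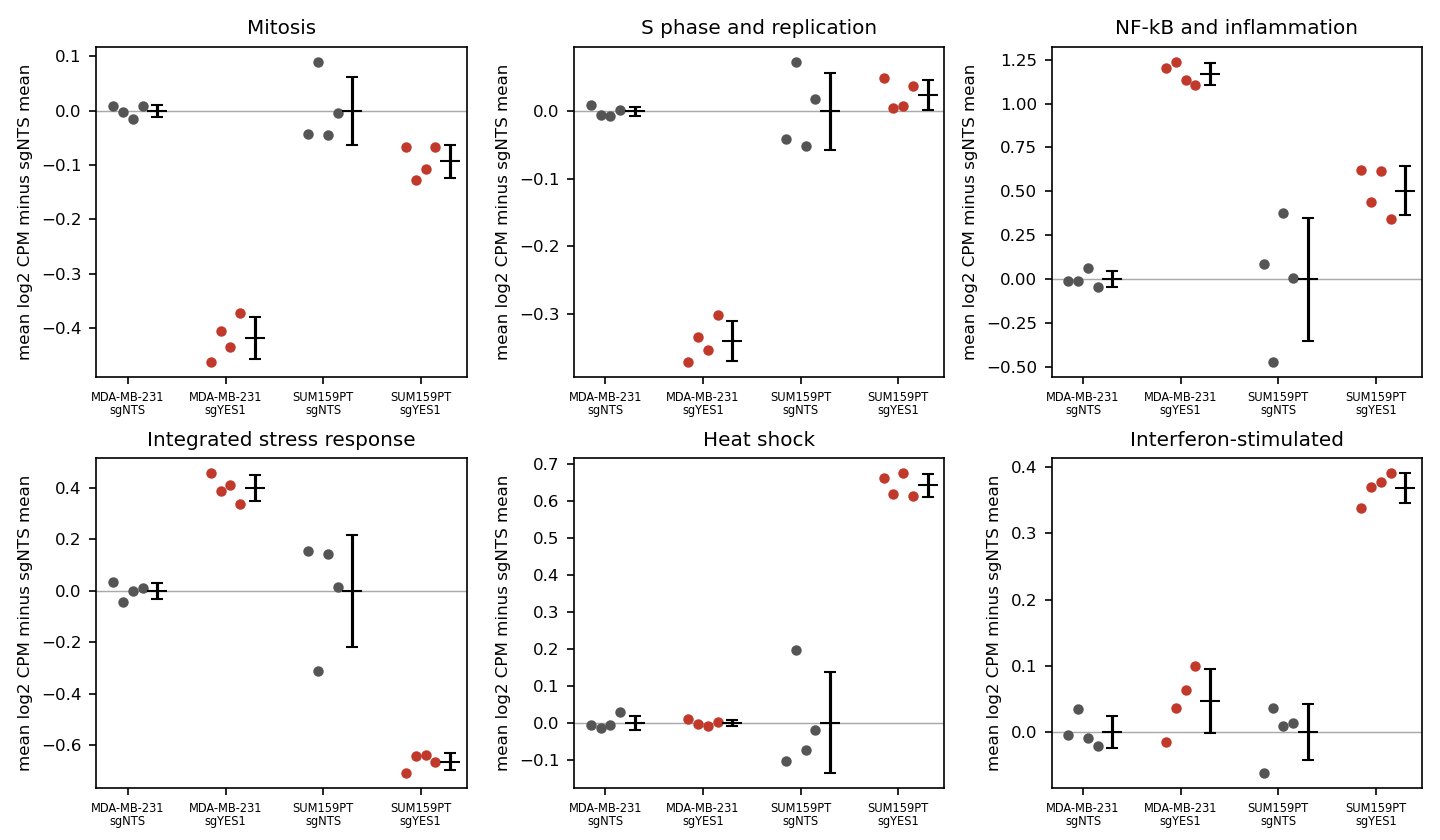
Mean log2 CPM of 6 gene lists in each of the 16 libraries, relative to the mean of the 4 sgNTS libraries of the same line. Points are libraries, bars give the mean and SD of 4 libraries, and each panel has its own y axis. In sgYES1 the mitosis score is -0.42 in MDA-MB-231 and -0.09 in SUM159PT, and the integrated stress response score is 0.40 in MDA-MB-231 and -0.66 in SUM159PT.

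The effects of sgYES1 were then compared between the lines with the interaction of line and guide. The 8 protein-coding genes with the smallest p of the difference, at a mean of at least 5 CPM in each line, moved in either direction. SESN2 rose 3.22-fold in MDA-MB-231 and had a log2 fold change of -1.11 in SUM159PT, a difference of -2.81 (SE 0.19, adjusted p = 1.82e-10; SUM159PT minus MDA-MB-231). GADD45A and GADD45B, growth-arrest genes induced by damage, had 0.98 and 0.88 in MDA-MB-231 and -0.92 and -0.46 in SUM159PT. DDIT4 had 0.14 in MDA-MB-231, a call that ended without sgNTS replicate 2 or 4 or sgYES1 replicate 3 or 4 (adjusted p 0.0566 to 0.0804), and differed by -2.14 (SE 0.12, adjusted p = 9.58e-12). FTL differed by -0.997 (SE 0.05), with no call in SUM159PT (adjusted p = 0.955), and FBXO32, a ubiquitin ligase of muscle atrophy, by -1.06. In the other direction, TGM2, a transglutaminase, rose 1.95-fold in SUM159PT and had -0.17 in MDA-MB-231, a difference of 1.12 (SE 0.06, adjusted p = 5.23e-12). DNAJB1 differed by 0.84 (SE 0.06), and its small call in MDA-MB-231 (-0.09) ended without sgNTS replicate 3 or 4 or sgYES1 replicate 1 or 3 (adjusted p 0.0584 to 0.0861).

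Of 16640 genes tested for a difference between the lines, 4085 passed, 2111 with a higher and 1974 with a lower log2 effect in SUM159PT. At a fold of at least 1.5 the count was 1224. Among the mitotic genes chosen beforehand, the log2 effect was higher in SUM159PT by 0.67 (SE 0.07) for PLK1, 0.52 (SE 0.08) for TTK and 0.42 (SE 0.06) for FOXM1, and 9 of the 11 genes differed. AURKB (0.15, adjusted p = 0.137) and KIF18A (0.10, adjusted p = 0.463) were not shown to differ.

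Lists were compared between the lines in the same way, a test added after the data had been seen. Of 31 lists, 15 differed, 10 with a higher and 5 with a lower effect in SUM159PT. The integrated stress response was lower in SUM159PT by a median of -0.84, with 35 of 39 members differing (camera adjusted p = 1.65e-24). Mitosis was higher by 0.33, with 67 of 90 members differing (6.77e-20), and S phase by 0.34, with 42 of 57 (1.57e-17). FOXM1 targets (0.34), heat shock (0.26), interferon-stimulated genes (0.25) and tubulins (0.28) were higher in SUM159PT, and NRF2 targets (-0.21), NF-kB and inflammation (-0.29) and ribosomal proteins (-0.16) were lower. With an estimated correlation camera called 0 of these lists (lowest adjusted p = 0.113), and 9 had an unadjusted p under 0.05. Other drawn groupings of the libraries gave up to 15 lists.

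**Figure D3:**
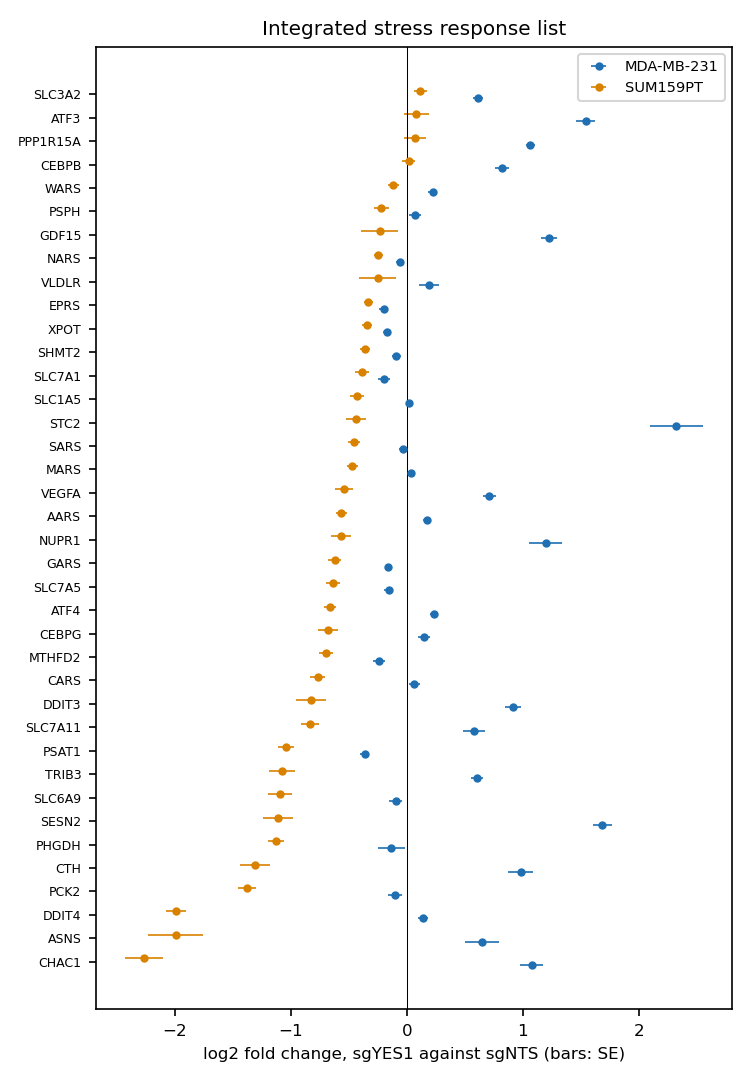
Log2 fold changes, sgYES1 against sgNTS, of the 38 integrated stress response genes tested in both lines, with their standard errors as bars (x axis). Blue marks MDA-MB-231 and orange SUM159PT, and genes are ordered by the value in SUM159PT. SESN2 stands at 1.69 in MDA-MB-231 and -1.11 in SUM159PT, and CHAC1 at 1.08 and -2.27.

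Some genes changed in the same direction in both lines. ARC rose 9.18-fold in MDA-MB-231 and 6.52-fold in SUM159PT, RRAD 3.98-fold and 4.98-fold, and ANGPTL4, an inhibitor of lipoprotein lipase, 3.26-fold and 3.08-fold. CSF3 had log2 fold changes of 3.47 and 1.41, and in the same order SNAI1, a transcription factor of epithelial-mesenchymal transition, rose 4.22-fold and 2.70-fold, AKR1C1, an aldo-keto reductase with close paralogs, 2.85-fold and 2.29-fold, SAA1 2.40-fold and 3.84-fold, and SAA2 3.90-fold and 4.53-fold. Among protein-coding genes within the same limits in each line, ranked by the smaller of both changes, the largest shared falls besides that of YES1 were those of ITGB4, the integrin of hemidesmosomes (-0.71 in MDA-MB-231 and -1.01 in SUM159PT), SHOC2, a scaffold of Ras and RAF signaling (-0.62 and -0.81), STARD4, a cholesterol transport protein (-0.66 and -0.74), CAV1 (-0.92 and -0.57), FRMD5 (-0.58 and -0.66), CPED1 (-0.71 and -0.58) and DENND6A (-0.58 and -0.58).

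Of 13390 genes tested in both lines, 1109 rose in both, where independent lists would share 561, and 1146 fell in both, where 635 would be shared. A further 261 rose in MDA-MB-231 and fell in SUM159PT, where 561 would be shared, and 332 did the opposite, where 635 would be. At a fold of at least 1.5 in each line, 214 rose and 19 fell in both, where independent lists would share 34 and 4. At that fold, 19 rose in MDA-MB-231 and fell in SUM159PT and 10 did the opposite, where 17 and 8 would be shared. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.385 (jackknife SE over libraries 0.0268) and a Spearman rho of 0.314. Other drawn groupings of the libraries gave a Pearson r of up to 0.3085.

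**Figure D4:**
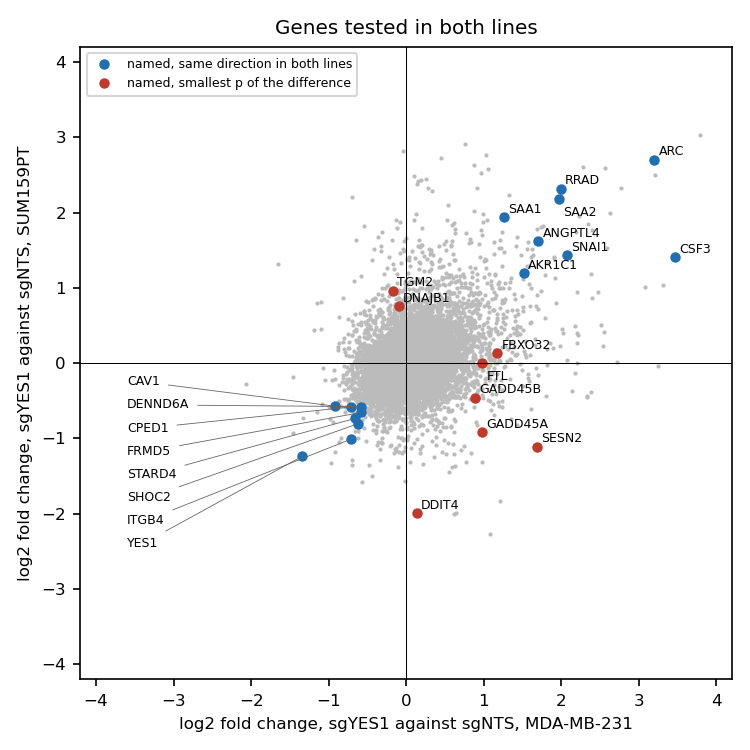
Log2 fold changes, sgYES1 against sgNTS, of the 13390 genes tested in both lines, MDA-MB-231 on the x axis and SUM159PT on the y axis. Blue points are the named genes that changed alike in both lines and red points the named genes with the smallest p of the difference, and 5 genes lie outside the plotted range. YES1 stands at -1.34 and -1.24, and DDIT4 at 0.14 and -1.99.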

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

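Of the tests below, the interaction test of single genes and the comparisons of a list with matched random lists were chosen before the result was seen. Chosen afterwards were the difference between lines of each list, the ratio of YES1 changes, the S-phase value, the leukocyte gain and the interferon interval.

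Dixon's test for a sample far from the others passed in 0 of 40 groups of 4 values, but with 4 values it passes only where 1 gap takes up most of the range, so it excludes little. SUM159PT sgNTS replicate 2, which stood apart from the other 3 sgNTS libraries, had gaps of 0.701 of the range for the integrated stress response, 0.718 for heat shock and 0.564 for NF-kB and inflammation. What brought the results below forward was a difference between the cell lines in the effect of sgYES1, tested as the interaction of line and guide. Of the 86 genes named by the rule in the text and tested in both lines, 70 differed, 37 with a higher and 33 with a lower log2 effect in SUM159PT. The rule picks genes partly by the p of this difference and by large changes in these same data, so a high share is built in. Over all genes tested, 4085 of 16640 differed, or 24.5%.

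Gene lists that were higher in SUM159PT differed by medians of 0.33 (mitosis), 0.34 (S phase and replication), 0.34 (FOXM1 targets), 0.26 (heat shock), 0.28 (tubulins and taxane transport), 0.25 (interferon-stimulated genes), 0.31 (epithelial genes, adjusted p = 0.00136), 0.11 (ribosome biogenesis, 0.00181), 0.16 (serum response and actin, 0.014) and 0.18 (homologous recombination, 0.0466). Lists that were lower in SUM159PT differed by -0.84 (integrated stress response), -0.16 (ribosomal proteins), -0.21 (NRF2 targets), -0.29 (NF-kB and inflammation) and -0.26 (ERK targets, 0.02). With an estimated correlation camera called 0 of these 15 lists, with a lowest adjusted p of 0.113 and 9 lists at an unadjusted p under 0.05.

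Differences of named genes are log2 effects in SUM159PT minus those in MDA-MB-231, each past the threshold of the edgeR interaction test. Among kinases and regulators the differences were 0.27 (LYN), 0.22 (CSK) and -0.24 (AXL). For mitotic genes they were 0.39 (AURKA), 0.35 (BUB1), 0.34 (CCNB1), 0.40 (CDC20), 0.33 (CENPE), 0.42 (FOXM1), 0.56 (KIF20A), 0.39 (MAD2L1), 0.67 (PLK1) and 0.52 (TTK). In genes of replication and repair they were 0.27 (BARD1), 1.12 (E2F8), 0.61 (MCM6), 0.20 (RBBP8), 0.66 (RRM2) and 0.70 (TYMS). Among genes of the cytoskeleton and membrane the differences were 0.34 (CAV1), 0.26 (CNN3), 0.53 (LYPD6), 0.81 (TMEM238), 0.46 (TUBA1B), 0.44 (TUBB) and 1.12 (TGM2). For chaperone genes they were 0.82 (DNAJA1), 0.84 (DNAJB1), 2.04 (HSPA1A), 2.17 (HSPA1B) and 1.47 (HSPA8). In antiviral and interferon-induced genes they were 0.39 (HELZ2), 1.87 (IFIT3) and 2.22 (OASL). Among inflammatory and acute-phase genes the differences were 1.13 (C1S), -2.07 (CSF3), -1.44 (CXCL8), 0.63 (ICAM1), -2.08 (IL1A), -2.70 (IL1B), -2.01 (IL6), 1.55 (PTGES), 0.66 (SAA1) and -0.46 (SOD2). For genes of the stress response and amino acid synthesis they were -2.65 (ASNS), -1.47 (ATF3), -3.35 (CHAC1), -2.30 (CTH), -2.14 (DDIT4), -1.91 (GADD45A), -1.35 (GADD45B), -1.47 (GDF15), -1.29 (PCK2), -1.01 (PHGDH), -1.01 (PPP1R15A), -0.69 (PSAT1) and -2.81 (SESN2). In the other named genes they were -0.33 (AKR1C1), -0.68 (CYR61), -1.03 (DMBT1), -2.63 (EGR1), -1.06 (FBXO32), -1.21 (FOSB), -0.997 (FTL), -0.36 (HMOX1), -0.18 (RPL3), -0.15 (RPLP0), -2.32 (SCG5), -0.65 (SNAI1) and -1.98 (TSC22D3).

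Mitosis genes fell in MDA-MB-231 and fell less in SUM159PT. The level, length and GC content of the genes did not produce this: of 10000 matched random lists, 0% had a median as low as -0.46 in MDA-MB-231 (random median -0.07, range of the middle 95% -0.11 to -0.03) and 0% had a difference as high as 0.33 (random median 0.05). A weaker loss of YES1 mRNA in SUM159PT was also argued against, since the log2 change of YES1 there was 0.925 times that in MDA-MB-231 while the mitotic median shrank from -0.46 to -0.08. This speaks to mRNA only. No measure of YES1 protein was available, so an unequal loss of the protein stays open. A candidate explanation that stays open is a smaller share of cycling cells in MDA-MB-231 sgYES1, which needs S-phase genes to fall too, and their median was -0.30. No measure of cell number or cell cycle stage was available, and an effect of the line itself, which the design names, was not tested apart from it.

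Inflammatory genes rose in MDA-MB-231. RNA from leukocytes was argued against, since their low-level markers gained 2.12 CPM against 1672 CPM for the inflammatory list, or 0.127%. A tendency of genes at low level to rise was tested with matched random lists, of which 0% had a median as high as 0.87 (random median -0.01). The matching used the mean level over both guides, so members that started low were matched to genes at a higher level. Over all genes of the line, median log2 fold changes were 0.28 under 1 CPM and 0.13 at 1 to 10 CPM, both below 0.87. An interferon response to the transfected guide as large as the inflammatory rise was argued against in MDA-MB-231. The interferon list there had a median of 0.015 (SD of members 0.28, 13 up and 12 down). Resampling its members gave an upper bound of 0.11, which treats genes as independent and leaves out the spread between libraries. Between libraries, its mean score in sgYES1 was 0.05 ± 0.05 (SD, n = 4), against 1.17 ± 0.06 for the inflammatory list. Members of the interferon list went both ways, with IFIT3 at -0.32 and the highest, IRF1, at 0.65. In SUM159PT camera called that list upward (18 up and 2 down of 42, median 0.29, adjusted p = 6.15e-05, and 0.0868 with an estimated correlation). A weaker interferon response stays open in MDA-MB-231, as does a response to the loss of YES1. An effect of this guide other than on YES1 could not be tested with 1 guide.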

How the results depend on the processing

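The comparison of lists between the lines and its alternatives, and the alternatives run for each single list, were chosen after the data were seen; the others were chosen before.

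The counts of genes and the direction of YES1 held under other scalings, filters and tests within 1.5 times. Requiring a fold of at least 1.5 or 2 left 1389 and 536 genes in MDA-MB-231, 1054 and 382 in SUM159PT, 1224 and 568 that differed between the lines and 233 and 79 changed alike in both, since fewer genes can pass. An adjusted p under 0.01 left 2500 genes that differed and 1358 changed alike. The correlation of the lines was 0.314 as Spearman rho and 0.421 over genes called in either line. With an estimated correlation camera called 3 lists in MDA-MB-231, 0 in SUM159PT (2 at an unadjusted p under 0.05, 18 by fry) and 0 between the lines (9 at an unadjusted p under 0.05), as that setting widens the error of lists whose genes vary together. Fry called 22 lists in MDA-MB-231, as it asks only whether a list moves. Fry also placed ERK targets in MDA-MB-231 upward (adjusted p = 0.0361), where camera placed them downward without a call; the cause was not tested.

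Leaving out 1 library gave 5778 to 6582 genes in MDA-MB-231, 4880 to 5654 in SUM159PT, 3706 to 4365 that differed and 1955 to 2244 changed alike, with a correlation of 0.368 to 0.4003. It gave 13 to 14 lists in MDA-MB-231, 10 to 13 in SUM159PT and 14 to 15 between the lines, and YES1 at -1.35 to -1.32 in MDA-MB-231 and -1.26 to -1.21 in SUM159PT. The replicate number as a block gave 5901, 5886, 3817 and 2121 genes, although libraries of the same number did not go together (correlations of -0.11 to 0.04 in MDA-MB-231). The naming rule and the lists together gave 193 called genes in MDA-MB-231 and 171 in SUM159PT, more than the text names. Of these, 174 and 157 passed under each scaling, filter, test, set of samples and block in which they were tested, with 0 reversed. A setting that removed a gene or gave it no adjusted p was not counted against it. The rule picked large changes or small p, so a high share that held follows in part from the rule. An adjusted p under 0.01 left 179 and 159, a fold of at least 1.5 left 71 and 67, and a fold of at least 2 left 31 and 39. In data simulated at these depths, 77.0% and 82.8% of the 1.5-fold changes that passed the filter were recovered in MDA-MB-231 and SUM159PT. Depth itself was not varied, so its effect was not tested.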

Other observations

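The count of genes detected at matched depth and the tests on the genes beside YES1, other than that of neighbours elsewhere, were chosen after the result was seen. The regroupings of libraries were chosen before, other than that of the lists that differ between the lines, and so was the count of neighbours elsewhere, although the genes it starts from were picked after their values were seen.

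Counts below are over all genes, with the counts adjusted over the list alone given second where they differ. In MDA-MB-231, lists that camera did not call included those of p53 targets (11 up and 7 down of 28, 15 and 7 over the list alone, median 0.14, adjusted p = 0.0932), endoplasmic reticulum chaperones (10 and 4 of 25, 11 and 4, 0.11, 0.1, and 0.0487 with library totals), nuclear oxidative phosphorylation (3 and 13 of 46, 2 and 11, -0.04, 0.129, and 0.0274 without sgYES1 replicate 4), mesenchymal and matrix genes (15 and 8 of 31, 0.11, 0.177) and lysosome and autophagy (15 and 10 of 40, 16 and 10, 0.04, 0.286). Endothelial markers (3 and 1 of 5) had a median of 0.49 and adjusted p = 0.29. By library totals, ROBO4 stood at 41.9 and 61.0 CPM and ESAM at 105 and 89.2 CPM in sgNTS and sgYES1, 2 genes chosen after their values were seen. Interferon-stimulated genes (13 and 12 of 50, 0.015, 0.625), ribosomal proteins (14 and 9 of 78, 12 and 9, 0.04, 0.609), mitochondrially encoded genes (0 and 0 of 13, 0.07, 0.625), luminal markers (2 and 2 of 8, -0.11, 0.625), heat shock (4 and 6 of 19, 4 and 7, -0.03, 0.661), non-polyadenylated histones (1 and 1 of 12, 1 and 0, -0.13, 0.81) and the BCL2 family (6 and 7 of 24, 7 and 7, 0.01, 0.932) were not called. Median and mean pointed apart for epithelial genes (4 and 8 of 18, 4 and 9, -0.11 and 0.09, adjusted p = 0.461), hypoxia and glycolysis (7 and 10 of 35, 7 and 11, -0.02 and 0.02, 0.81), ERK targets (11 and 12 of 27, 11 and 13, -0.06 and 0.13, 0.932) and ribosome biogenesis (7 and 9 of 35, 8 and 9, -0.0029 and 0.02, 0.932). They also did so for Src-family kinases (0 and 3 of 7), which had a median of 0.02, a mean of -0.17 with YES1 included and adjusted p = 0.465.

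In SUM159PT, the lists not called included those of Src substrates and adhesion (7 up and 16 down of 36, 7 and 17 adjusted over the list alone, median -0.13, adjusted p = 0.058). That list passed without sgNTS replicate 4 (0.0479), sgYES1 replicate 1 (0.0406) or sgYES1 replicate 2 (0.046). ERK targets (7 and 15 of 27, -0.25, 0.154) passed without sgNTS replicate 2 (0.0166), and cholesterol synthesis (2 and 6 of 24, -0.08, 0.15) without sgYES1 replicate 4 (0.0343). Epithelial genes (6 and 1 of 13, 7 and 1, 0.11, 0.115), tubulins and taxane transport (10 and 5 of 25, 10 and 6, 0.08, 0.177), non-polyadenylated histones (4 and 1 of 16, 0.13, 0.299), endoplasmic reticulum chaperones (10 and 6 of 25, 0.06, 0.336), serum response and actin (4 and 9 of 27, -0.03, 0.374), the BCL2 family (9 and 6 of 24, 0.08, 0.542), mitochondrially encoded genes (2 and 2 of 13, 0.04, 0.606), luminal markers (3 and 1 of 6, 3 and 2, 0.06, 0.606), S phase (15 and 11 of 57, 16 and 11, 0.01, 0.925) and p53 targets (8 and 8 of 27, -0.03, 0.979) were not called. Median and mean pointed apart for NRF2 targets (9 and 7 of 27, -0.01 and 0.11, 0.546), hypoxia and glycolysis (8 and 9 of 35, -0.02 and 0.04, 0.966), mesenchymal and matrix genes (9 and 6 of 33, -0.05 and 0.19, 0.966), lysosome and autophagy (12 and 10 of 40, 12 and 12, -0.05 and 0.02, 0.979) and Src-family kinases (1 and 1 of 5, 0.10 and -0.17, 0.966). Endothelial markers in SUM159PT and leukocyte markers in both lines had fewer than 5 tested members and were not tested as lists.

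More genes were detected in sgYES1 after all libraries of a line were thinned to the same depth. In MDA-MB-231, 22568 ± 181 genes (SD, n = 4) were detected in sgNTS and 24068 ± 153 in sgYES1, and in SUM159PT 21551 ± 114 and 22411 ± 29.7 (exact permutation p = 0.0286 in each line, the smallest possible). Among genes under 1 CPM, 304 rose and 36 fell in MDA-MB-231 and 153 rose and 37 fell in SUM159PT, while above 10 CPM 1916 rose and 2988 fell and 2082 rose and 2427 fell. Olfactory receptor genes stood at 1.99 ± 0.51 and 2.36 ± 0.47 CPM in MDA-MB-231 (exact permutation p = 0.371) and at 10.4 ± 1.20 and 10.1 ± 0.792 CPM in SUM159PT (exact permutation p = 0.657).

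Genes beside YES1 on chromosome 18 also fell in both lines, and were chosen after their values were seen. ENOSF1 (670324 to 712676), an enzyme gene on the same strand, had log2 fold changes of -0.61 in MDA-MB-231 and -0.57 in SUM159PT, TYMS (657604 to 673578) -0.92 and -0.21, and its antisense gene TYMSOS (641320 to 658340) -0.92 and -1.19. On the other side, where YES1 ends at 812546, the 2 genes given lie much farther off. METTL4 (2537525 to 2571509) had -0.23 and -0.44 and SMCHD1 (2655738 to 2805017) -0.27 and -0.22. Falls were common over all genes tested, at 3402 of 15427 in MDA-MB-231 and 2859 of 14479 in SUM159PT.

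The fall of ENOSF1, TYMS and TYMSOS was weighed against 4 explanations. Of 13334 runs of 3 consecutive genes, 0.09% fell as far in both lines, but the run beside YES1 was picked after its values were seen, so chance neighbours stay open. In SUM159PT, ENOSF1 and TYMSOS fell further than TYMS (differences -0.36, SE 0.08, and -0.98, SE 0.24). This argues against reads of TYMS as the whole source of their falls there. The fall of TYMS could still come from reads shared with them, so reads shared between overlapping genes stay open in SUM159PT. Shared reads also stay open in MDA-MB-231, where ENOSF1 minus TYMS was 0.31 (SE 0.10). Loss of the chromosome end beyond YES1 was argued against in SUM159PT, where USP14 and THOC1, nearer the end, had a mean of -0.012. In MDA-MB-231 both were called lower (USP14 -0.23, edgeR adjusted p = 0.000149, and THOC1 -0.37, edgeR adjusted p = 0.000109). Their mean there of -0.30 was a smaller fall than the -0.61 of ENOSF1. Such a loss was therefore argued against as the whole cause in MDA-MB-231, and stays open as a part of it. Transcripts that run on from YES1 into ENOSF1 cannot be told apart from a lower level of ENOSF1 itself, since the loss of ENOSF1 was at most 35.3% of that of YES1 in CPM and strand is not settled.

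Regrouping set each result beside other splits of the same libraries. The 6607 genes of MDA-MB-231 were reached by 1 of 35 splits, the real one (highest other 0). The 5701 of SUM159PT were reached by 1 of 35 (highest other 1). Other splits mix the guides within a group, which widens its spread, so few calls there follow from any difference between the real groups. The splits speak only to the grouping of these libraries. A difference between cultures or transfections is not excluded, since the replicates are described as technical. With the same limit, the 2255 genes changed alike were reached by 1 of 100 drawn splits (highest other 0). The correlation of 0.385 was reached by 1 of 100 (highest other 0.309). The 4085 genes that differed were reached by 1 of 40 (highest other 3045). That 3045 came from a split that kept the real grouping of 1 line, and the 38 that kept neither reached 0. Exchanging guides removes the guide effect of a line, so these splits cannot test for an equal effect in both lines. No conclusion on the difference between lines is drawn from them. For the number of lists chance is not excluded: 13 lists in MDA-MB-231 were reached by 9 of 35 splits (highest other 14), 12 in SUM159PT by 2 of 35 (highest other 12) and 15 between the lines by 3 of 40 (highest other 15).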
